A study of Homo sapiens with 2 samples.

How the data were processed

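Human bronchial epithelial cells were labelled for 20 min with 500 uM 4-thiouridine (4sU), a uridine analogue that cells build into RNA as it is made. Per the labels' protocols, nuclei were isolated, labelled RNA was purified from nuclear RNA, a poly(A) tail was added in vitro with a bacterial poly(A) polymerase, and the RNA itself was read on Nanopore flow cells as 2 libraries of 1 group. The deposited data were 1 set of transcript models (isoforms) made from both libraries together and 1 classification of the same isoforms, so neither file held values per library.

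The authors' isoform file gives the genome positions of the exons of each isoform and, per the file headers, names FLAIR as its source. FLAIR corrects splice sites of long reads and collapses reads into isoforms. The names of the deposited files state that isoforms were corrected, collapsed and kept from a minimum of 3, without saying of what, and that the classification was made with SQANTI2. Builds hg19 and hg38 are listed in the submitters' processing notes without a role. The aligner, the reference annotation and the versions of these programs are not given in the sources used here. The authors' classification gives, per the file headers, lengths, exon numbers, distances in nt and the percent of A in the 20 genomic bases after the 3' end. Its columns for read support and expression held no values, so the depth behind each isoform is unknown and a number of isoforms is no measure of expression.

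Both files were matched isoform by isoform. The positions were read as GRCh38 (hg38), because 98.8% of the distinct splice junctions matched annotated junctions of that build. Gene models were GENCODE release 44, with the GRCh38 positions that its lifted version records for 1633539 of 1650930 exons (98.95%). Most small RNA genes have no such position and were looked up by position in the RefSeq gene table of GRCh38.p14, which gives no strand. No genome sequence of this build was used here, so the planned analyses of splice site motifs and of AG followed by GT at intronic sites were not run.

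Isoforms of the 22 autosomes and chromosome X were analysed, 3250 in all. Chromosome Y and the XIST locus were left out everywhere, and mitochondrial isoforms were only counted. Strand was taken from the isoform file. An isoform was given to the gene on its strand with which it shared most junctions or most exonic sequence. Spliced isoforms were sorted by whether their junctions followed a whole annotated chain of introns, part of one, a combination that no single transcript holds, or an unannotated junction. Single-exon isoforms were called exonic when 95% of their length lay in annotated exons. An intron was called kept when an annotated intron of 50 nt or longer lay inside an exon with 10 nt or more of exon on both sides. Kept and removed introns were compared for the Ensembl canonical transcript of each protein-coding gene, 1 intron in 1 isoform being the unit. Isoform ends were compared with annotated transcript starts and ends on the same strand in a window of 100 nt. Distances were computed from coordinates for every isoform, because the classification gives them for 1268 isoforms only.

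The design held 1 group, so nothing was compared between samples and no p-values were computed. Shares carry exact 95% binomial intervals (Clopper-Pearson), which cover counting error only, since isoforms of 1 gene are not independent and libraries were pooled. Each gene list was described by the number of its members with an isoform and by its percentile among 10000 random lists of the same size drawn from protein-coding genes of like gene length (10 length bins). The draws were not matched for expression, and lists with non-coding genes were also set against protein-coding ones. Lists of secretory markers, endothelial markers, immediate early and stress genes and nuclear non-coding RNAs held 7, 4, 33 and 19 genes. Of these 6, 3, 32 and 16 were in the gene models used, and the rest were left out. The design, the gene lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with most isoforms, the 10 genes with most isoforms keeping an intron, up to 4 members of each list with most isoforms, the genes of the 5 longest isoforms and of the 10 longest introns spanned by 1 junction, RAB7A, and list members with an unannotated junction. Markers without an isoform, IER2, KLF4, MALAT1 and the small RNA genes were named after their values were seen.

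The sorting steps were tested on simulated data built from annotated transcripts. Of 200 simulated isoforms with a whole annotated chain, 99.5% were recovered, as were 99.5% of 200 with part of a chain, 100% of 200 with a kept intron, 100% of 199 with an unannotated junction and 100% of 200 set on the wrong strand. For part of a chain, recovered means sorted as part of a chain or as a whole chain. On the wrong strand, recovered means sorted as having an unannotated junction. The gene was found for 0% of the isoforms on the wrong strand, against 100% of every other kind. Simulated isoforms were built from the same gene models, so genes that the models lack were not tested. Analyses ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, intervaltree 3.1.0 and matplotlib 3.10.9. Alternatives covered the isoforms counted, the weight of each gene, the windows at isoform ends, the definition of a kept intron and the match of junctions to the annotation.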

Results

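The data described nascent RNA of human bronchial epithelial cells, read as long single molecules. Both libraries came from nuclear RNA labelled with 4sU for 20 min, and 1 pooled set of 3250 isoforms was analysed. Of these, 1594 lay on the plus strand and 1656 on the minus strand. Their median length was 1250 nt, and 1846 were spliced. The isoforms fell in 1506 genes of their own strand, of which 1337 were protein-coding and 128 were long non-coding RNA genes. A single isoform was listed for 993 genes and 5 or more for 109. With no read numbers per isoform or per library, there was no replicate error to compare with, and the depth was unknown.

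The first question was which genes these nascent isoforms came from. SNHG1, a host gene of small nucleolar RNAs, had the most isoforms, with 20. It was followed by IGF2R, the receptor that carries mannose 6-phosphate tagged enzymes, with 17, and by PPP1R10, a nuclear regulator of protein phosphatase 1, with 16. CCNL1 (a cyclin linked to splicing), DDX5 (an RNA helicase), NFKBIZ (an inducible regulator of NF-kB targets) and POLR2A (the largest subunit of RNA polymerase II) had 15 each. The translation initiation helicases EIF4A1 and EIF4A2 and the p53 regulator MDM2 had 13 each. The longest isoforms were a single exon of 7644 nt in ARFRP1, a spliced isoform of 7025 nt in RABL6, a single exon of 6784 nt on chromosome 21 from 8205941 to 8212724 in a ribosomal RNA gene, a spliced isoform of 6116 nt in SRSF10 and one of 5707 nt in SERPINB2.

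Most markers of basal airway epithelium had an isoform. Of 15 basal markers 12 had an isoform, against a median of 1 in random lists (percentile 100). LAMB3, a laminin chain of the basement membrane, had 12 isoforms, LAMA3 had 6, and the basal keratins KRT17 and KRT5 had 5 each. No isoform was listed for KRT15, NGFR and TP63, which are also basal markers. None of the secretory, ionocyte and neuroendocrine, fibroblast or endothelial markers had an isoform, over 6, 6, 7 and 3 genes. Random lists also had a median of 0 (percentiles 29.96, 31.22, 28.8 and 41.8), so these counts do not show that such cells were absent. Of 8 ciliated cell markers only TUBB4B, a tubulin that many cell types make, was listed, with 4 isoforms. Of 6 blood cell markers only HBB was listed, with 1 single-exon isoform. Among genes of keratinocyte junctions and matrix 22 of 32 had an isoform (percentile 100), led by MYH9 with 10, FLNA with 9, and CD44 and PLEC with 5 each.

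Immediate early and stress genes were nearly all present. The list holds fast-responding genes and also constitutive ones such as HSPA8. Of its 33 listed genes 32 were in the gene models used. Of these, 30 had an isoform and 23 a spliced one, against a median of 2 in random lists (percentile 100). MDM2 had 13 isoforms, the heat shock cognate HSPA8 had 7, and the growth factor AREG and the transcription factor FOS had 6 each. IER2 and KLF4 had none. Isoform number is no measure of level, so no levels were compared.

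Genes of the RNA and protein synthesis machinery were also widely covered. Ribosomal protein genes had an isoform for 69 of 83 members, with RPS2 at 11, RPL3 and RPS9 at 8 each and RPL17 at 6. Host genes of small nucleolar RNAs had one for 21 of 24, with SNHG1 at 20, EIF4A2 at 13, GAS5 at 9 and NOP56 at 8. SR proteins and other splicing factors had one for 27 of 35, with DDX5 at 15, HNRNPA2B1 at 12, SRSF7 at 10 and HNRNPA1 at 6. Each of these lists lay at percentile 100 of its random lists, whose medians were 7, 2 and 3. The random lists were not matched for expression, so this does not set these lists apart from other expressed genes.

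Histone genes and nuclear non-coding RNAs were also covered. The list of replication-dependent histone genes, which by its symbol rule also took in the replacement histone H1-10, had an isoform for 41 of 69 members, against a median of 5 in random lists (percentile 100). H4C14 had 3 isoforms, and H2AC6, H2BC21 and H2BC5 had 2 each. The longest isoform of H4C14 was 1639 nt, and whether histone isoforms ended at the natural 3' end was not tested. Of 16 nuclear non-coding RNA genes in the gene models, out of 19 listed, 11 had an isoform, 9 of them without any spliced one. RN7SL1 and RN7SL2 were listed but missing from the gene models, and isoforms lay over both by position. MIR31HG and NEAT1 had 4 isoforms each and MIR17HG and MIR22HG had 3 each. MALAT1, an abundant nuclear RNA, had 1. Mitochondrial RNA, made outside the nucleus, gave 2 isoforms.

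The next question was how the isoforms are built. On the strand of the isoform file, 43.2% of isoforms had 1 exon (95% interval 41.5 to 44.9). Of the spliced isoforms, 31.9% (29.8 to 34.1) held a whole annotated chain of introns and 50.7% (48.3 to 53.0) held part of one. A combination of annotated junctions that no single transcript holds made up 14.1% (12.6 to 15.8), and 3.30% (2.54 to 4.22) had an unannotated junction. Some of these junctions lay where the gene models used here hold no gene of that strand. Of the single-exon isoforms, 17.4% were exonic, 16.0% contained a whole intron, 24.6% joined exon with part of an intron or flank, 12.3% lay within an intron, 11.6% lay opposite a gene and 18.2% lay outside the gene models. Of the 255 in the last class, 64 lay over ribosomal or small RNA genes of the RefSeq table. MDM2 had 10 single-exon isoforms out of 13 and IGF2R had 10 out of 17, while all isoforms of EIF4A1, RPS2, GAPDH and EIF4G2 were spliced.

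The authors' classes split by strand. In the authors' classification, 38.8% (37.1 to 40.5) of isoforms were called antisense, and this share was 5.96% (4.85 to 7.24) of plus-strand and 70.4% (68.1 to 72.6) of minus-strand isoforms. All 20 isoforms of SNHG1 and all 15 of DDX5 and of CCNL1, which are minus-strand genes, were called antisense, and none of EIF4A1, NFKBIZ, POLR2A or IGF2R, which lie on the plus strand. The full splice match class held 24.1% (22.01 to 26.3) of plus-strand and 1.45% (0.931 to 2.15) of minus-strand isoforms, and the incomplete splice match class 27.5% and 0.181%. A 5' end within a peak of capped RNA starts was recorded for 24.1% and 1.63%. The classification recorded the plus strand for 99.8% of the minus-strand isoforms, so its classes were not used for the values by gene.

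**Figure D1:**
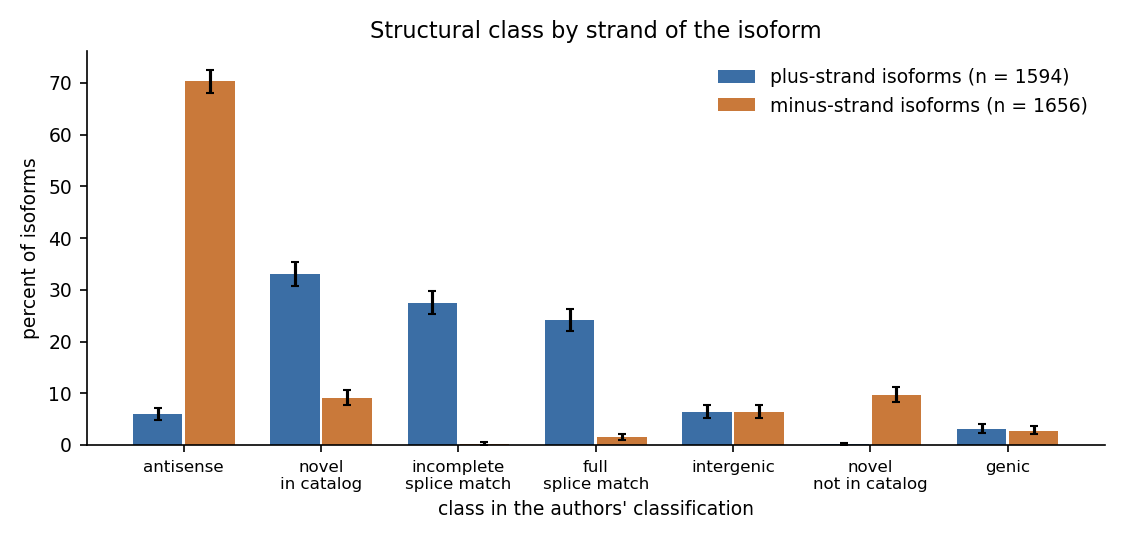
Percent of isoforms (y axis) in each class of the authors' classification (x axis), for 1594 plus-strand and 1656 minus-strand isoforms; error bars are exact 95% binomial intervals. The antisense class holds 70.4% of minus-strand and 5.96% of plus-strand isoforms, and both splice match classes are almost empty on the minus strand.

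Nascent RNA can be caught before its introns are removed, and the next comparison asked which introns were kept. Of the spliced isoforms, 44.5% (42.2 to 46.8) kept at least 1 annotated intron. The share was 25.9% when only introns removed in another isoform counted, 18.3% for introns of 500 nt or longer and 42.2% on the plus strand alone. The authors' own subcategory gave 2.93%, and 6.09% (4.61 to 7.88) on the plus strand alone, so their strand column does not account for the gap. SNHG1 kept one in 17 of 18 spliced isoforms, DDX5 in 13 of 14, EIF4A1 in 11 of 13, EIF4A2 in 11 of 12, and RPS2 and EIF4G2 in all 11. NFKBIZ kept one in 11 of 12, POLR2A in 11 of 14, and CCNL1 and the glycolytic enzyme gene GAPDH in 9 of 13 and 9 of 11. MDM2 kept none in its 3 spliced isoforms.

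The share was also taken by gene group, and differences between groups were not tested. Among host genes of small nucleolar RNAs 77.2% (67.2 to 85.3) of 92 spliced isoforms kept an intron, and among splicing factor genes 73.4% (62.3 to 82.7) of 79 did. Ribosomal protein genes kept one in 54.7% (46.3 to 62.8) of 150 spliced isoforms and immediate early and stress genes in 40.7% (27.6 to 55.0) of 54. Basal markers kept one in 42.9% (26.3 to 60.6) of 35 and genes of keratinocyte junctions and matrix in 44.2% (29.1 to 60.1) of 43. With each gene counted once the order of the first 2 groups turned, with 62.0% for host genes of small nucleolar RNAs and 76.8% for splicing factor genes, while ribosomal protein genes stood at 40.3% and immediate early and stress genes at 34.5%. Counting only introns of the canonical transcript of protein-coding genes, splicing factor genes kept 16.1% (12.5 to 20.2), against 15.3% in other genes at the same intron lengths. Ribosomal protein genes kept 17.9% (14.97 to 21.04) against 14.6%, and immediate early and stress genes 15.5% (10.2 to 22.2) against 14.6%. Only 9 host genes of small nucleolar RNAs entered this count, since non-coding ones such as SNHG1 and GAS5 were left out, and they kept 22.4% (17.3 to 28.2) against 16.7%. With canonical transcripts of every gene type, 19 host genes kept 29.5% (25.2 to 34.0) against 17.1%.

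Kept introns were short. In 1025 protein-coding genes, 1044 of 7935 canonical introns in spliced isoforms were kept, or 13.2% (12.4 to 13.9), and the kept ones had a median of 221.5 nt against 588 nt for removed ones. The kept share fell from 22.4% (20.6 to 24.2) at 50 to under 200 nt to 17.4% (15.7 to 19.3) at 200 to under 500 nt, 9.38% (8.29 to 10.6) at 500 to under 2000 nt and 0.431% (0.158 to 0.936) at 2000 nt or longer. First introns were kept in 9.64% (7.77 to 11.8), internal ones in 14.2% (13.3 to 15.1) and last ones in 10.1% (8.24 to 12.1), against 8.53%, 13.8% and 13.5% of all introns at the same lengths. The kept introns were 837 distinct introns of 347 genes, and 451 of them were removed in another isoform. With each gene counted once the kept share was 9.80%, and with genes of every type, 1053 in all, it was 13.7% (12.99 to 14.5).

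**Figure D2:**
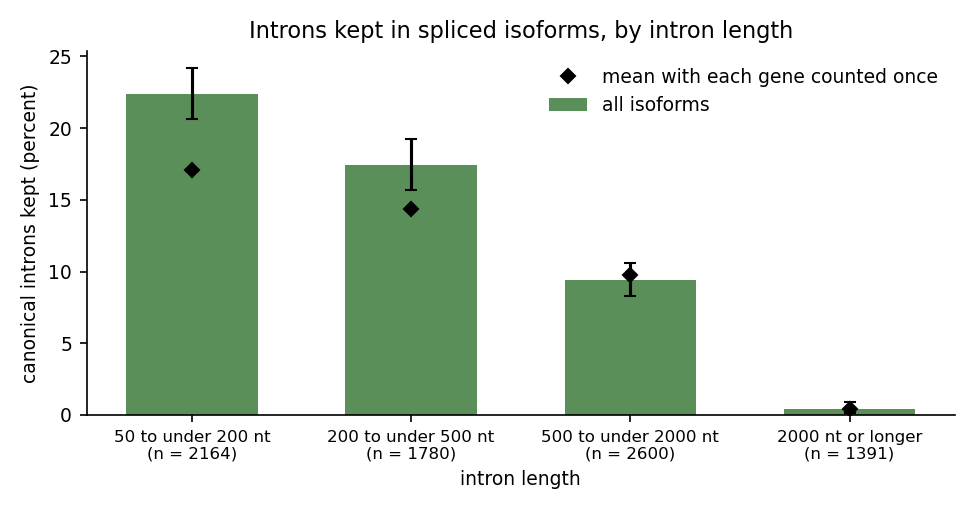
Percent of canonical introns of protein-coding genes kept in spliced isoforms (y axis) by intron length (x axis); n is the number of introns over all isoforms, bars show all isoforms with exact 95% binomial intervals, and diamonds show the mean with each gene counted once. The share falls from 22.4% at 50 to under 200 nt to 0.431% at 2000 nt or longer.

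Single introns were kept and removed in isoforms of the same gene. Intron 9 of 10 of EIF4A1, 248 nt on chromosome 17 from 7577917 to 7578164 (GRCh38), was kept in 7 isoforms and removed in 2. In the same gene intron 6 was removed in all 11 isoforms that span it and intron 4 in all 10. Intron 5 of 6 of RPS2, 79 nt on chromosome 16 from 1962657 to 1962735, was kept in 7 isoforms and removed in 4. Intron 4 of 8 of GAPDH, 129 nt on chromosome 12 from 6536791 to 6536919, was kept in 6 and removed in 5. Intron 7 of 12 of DDX5, 89 nt, was kept in 4 and removed in 5.

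**Figure D3:**
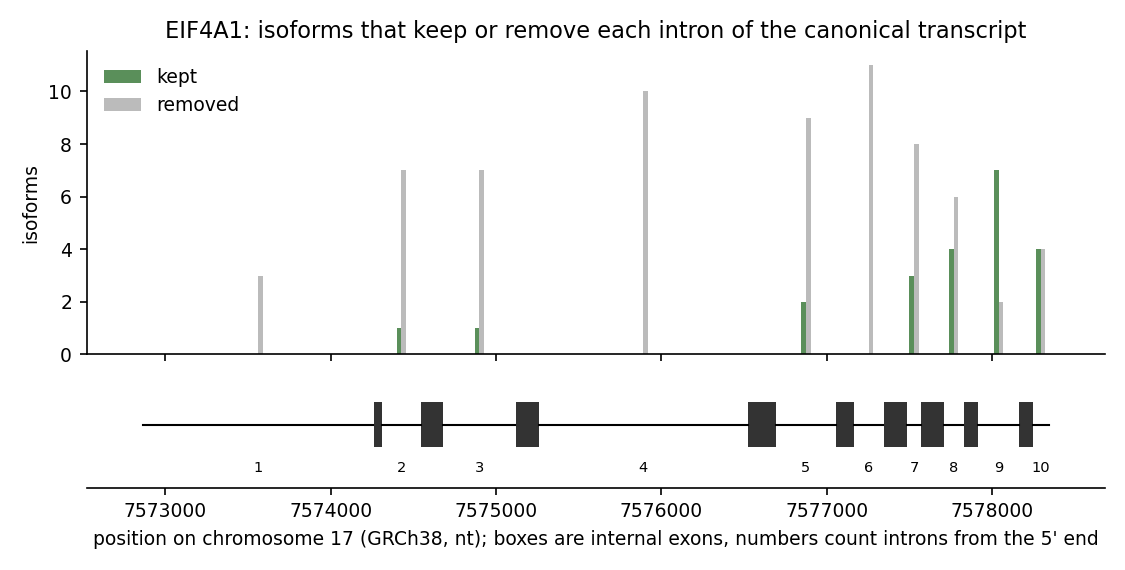
Number of EIF4A1 isoforms (y axis) that keep or remove each intron of the canonical transcript, drawn at the intron's midpoint on chromosome 17 (x axis, GRCh38, nt), above a map with internal exons as boxes and introns numbered from the 5' end. Intron 9 is kept in 7 isoforms and removed in 2, and introns 1, 4 and 6 are kept in none.

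The series title names recursive splicing, in which a long intron is taken out in pieces, so junctions were searched for sites inside introns. Of 5414 distinct junctions 98.8% (98.5 to 99.1) were annotated. Another 53 joined annotated sites in an unannotated pair, 3 had 1 annotated site and 10 had none. Of these 10, all but 1 lay where the gene models used here hold no gene of that strand. There, gaps in the gene models and unannotated splicing cannot be told apart. List members with an unannotated junction were DDX5, HNRNPK, CLK1, SRSF5, SNHG1, RPL3, AREG, TXNIP, H4C14 and H4C15. An annotated site was joined to an unannotated one 50 nt or more inside an annotated intron in 2 junctions, or 0.0369% (0.00447 to 0.133), in the histone gene H4C14 on chromosome 1 from 149833865 to 149834134 and in TXNIP, a regulator of thioredoxin, on chromosome 1 from 145995477 to 145996016. In both the unannotated site was the 5' splice site. Of the 10 junctions with no annotated site, 1 had its 3' splice site inside an annotated intron, by 1104 nt, in ZCCHC8 on chromosome 12 from 122498868 to 122500639; this gene was named after its values were seen, and both of its sites lay within 10 nt of those of an annotated junction.

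Long genes known for recursive splicing were not covered. None of the 11 members of that list, among them ANK3, CADM1, CADM2 and HS6ST3, had an isoform, which random lists of like gene length also gave (median 0, percentile 39.15), and RAB7A had none. The longest junction joined exons of RTN4, a membrane protein of the endoplasmic reticulum, over 62046 nt, followed by the actin cross-linker ACTN1 over 53279 nt, the proteasome genes PSMD1 over 51554 nt and PSMD14 over 48604 nt, and JMJD1C over 47319 nt. These 5 junctions were annotated. Splice sites had been corrected by the authors' software before these files were made, and the search covered only sites left after that step.

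The last comparison asked where isoforms begin and end. Of all isoforms, 45.5% (43.8 to 47.2) began within 100 nt of an annotated transcript start and 44.8% (43.1 to 46.5) ended within 100 nt of an annotated end. For spliced isoforms the shares were 62.6% (60.3 to 64.8) and 61.8% (59.5 to 64.0), and for single-exon isoforms 23.01% (20.8 to 25.3) and 22.5% (20.3 to 24.8). Of spliced isoforms 41.9% began and 50.9% ended within 1 nt of an annotated position, against 10.0% and 11.4% of single-exon ones. These are ends of collapsed isoform models, not of single reads. Whether the software set any of them to annotated positions was not tested. Spliced isoforms that kept an intron ended near an annotated end in 67.1% (63.8 to 70.3) and those that kept none in 57.5% (54.4 to 60.5). They began near an annotated start in 60.8% (57.3 to 64.1) and 64.0% (61.0 to 66.9), respectively.

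Many of the other 3' ends lay at splice sites. Of the 1794 isoforms that ended over 100 nt from an annotated transcript end, 352 or 19.6% (17.8 to 21.5) ended within 2 nt of the last base of an exon that precedes an annotated intron, 277 of them exactly there. Ends moved by 20 nt gave 0.502%. By strand, the share of unmoved ends was 16.1% (13.7 to 18.7) on the plus and 23.1% (20.4 to 25.9) on the minus strand. At 5' ends, 3.89% (3.04 to 4.90) lay within 2 nt of the first base of an exon, against 0.451% for moved ends. Such 3' ends made up 42.1% (38.4 to 45.8) in spliced and 5.06% (3.83 to 6.53) in single-exon isoforms, and came from 263 genes. PPP1R10 had 10 of them, NFKBIZ 7, POLR2A 6 and IGF2R 5. This comparison was added after the data were seen.

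**Figure D4:**
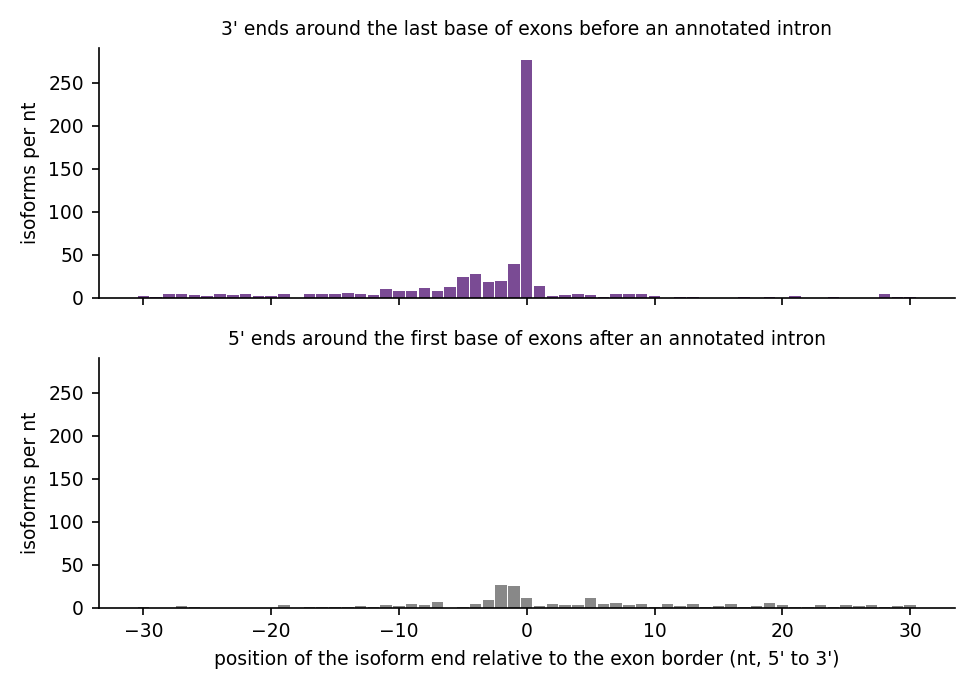
Number of isoforms (y axis) by the position of their end relative to an exon border (x axis, nt), for 3' ends around the last base of exons before an annotated intron (top) and 5' ends around the first base of exons after one (bottom), leaving out ends within 100 nt of annotated transcript ends or starts. The 3' ends peak at position 0 with 277 isoforms, and the 5' ends reach at most 26 at any position.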

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

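Signals in parts of the data that the comparisons above did not use are given here as values, and these counts were chosen after the data were seen. A count above 3, the limit that a count of 0 allows, set them apart, and no biological explanation was tested. Of the single-exon isoforms, 22 lay over 45S ribosomal RNA genes on chromosome 21, and 25 lay over 20 genes of U1, the small nuclear RNA that binds 5' splice sites. The authors' classification placed 7 isoforms on an unplaced scaffold, and the isoform file placed all 7 on chromosome 21 before position 9000000. Ribosomal and U1 genes exist as near-identical copies, so the copy an isoform was placed in is uncertain.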

How the results depend on the processing

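Over 26 results, 71 alternatives were run, of which 27 stayed within the 95% interval of the main value and 44 moved beyond it. The cause was not tested. Alternatives with plus-strand isoforms only, the authors' distances, introns removed elsewhere, each kept canonical intron, the order of kept introns and the ends at exon borders were added after the data were seen. Counting spliced isoforms only, the authors' classes moved to 41.7% antisense, 15.2% full splice match, 20.3% incomplete splice match, 14.0% with known sites in a new combination, 8.78% with new sites, and 0% genic and intergenic. Counting each gene once gave 35.9% antisense, 13.8% full splice match, 18.5% in the class of known sites and 10.5% intergenic. The class of known sites held 677 isoforms, of which only 259 were spliced, so most of it was single-exon isoforms. On the plus strand alone the shares were 5.96% antisense, 24.1% full splice match, 27.5% incomplete splice match, 33.0% in the class of known sites and 0.125% new sites. The single-exon share was 50.3% with each gene counted once. Near annotated starts lay 62.6% of spliced isoforms, 42.5% with each gene counted once, 42.6% within 50 nt, 57.5% within 500 nt and 32.0% by the authors' distances, and near annotated ends 61.8%, 40.8%, 42.3%, 58.4% and 32.3%. The share of spliced isoforms keeping an intron was 40.9% with 50 nt of exon on both sides, 39.1% for introns of protein-coding transcripts, 18.3% for introns of 500 nt or longer, 33.2% with each gene counted once, 25.9% for introns removed in another isoform and 2.93% by the authors' own subcategory, or 6.09% on the plus strand alone. Annotated junctions were 99.1% when counted per isoform, and sites 500 nt or more inside an intron were 0%. Requiring a spliced isoform left 0% of blood cell markers, 71.9% of immediate early and stress genes, 12.5% of nuclear non-coding RNA genes and 7.25% of histone genes. Ends at exon borders made up 15.4% when exact, 16.6% over 1000 nt from annotated ends and 16.6% with each gene counted once, and canonical introns kept were 9.80% with each gene counted once. Leaving out isoforms with 60% or more A after the 3' end was run for the classes, the single-exon share and the ends near annotated starts and ends, and moved none of them beyond its interval; which end that column was read from on the minus strand was not checked. Not run were a stricter minimum of reads, weighting by reads and leaving out each replicate, which need values per read or library, and the alternatives on splice site motifs and on AG followed by GT, which need genome sequence of this build. No paired analysis was possible because there was 1 group.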

Other observations

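Small nuclear RNAs were read past their annotated 3' ends; the genes named in this paragraph and the next were chosen after their values were seen. The gene table used for them gives no strand, so 5' and 3' ends of these genes were read in the direction of the isoform. Of 48 isoforms that began within 20 nt of the 5' end of a small nuclear RNA gene, 42 ended over 50 nt after the gene and 6 ended within 20 nt of its 3' end. All 25 U1 isoforms began within 20 nt of the gene's 5' end, and 21 of them ran 214 to 726 nt past it, with a median of 425 nt. RNU2-2, RNU4-2, RNU5B-1 and RNU12, of the U2, U4, U5 and U12 families, ran 921, 196, 714 and 559 nt past the gene. By contrast RN7SK, the RNA that holds back the elongation factor P-TEFb, and RMRP, the RNA of RNase MRP, ended within 2 nt of theirs. These isoforms were 330 and 266 nt long, and U1 isoforms that ended near the gene's 3' end 163 to 166 nt. Whether RNA length affected which ends were listed was not tested.

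Isoforms also lay over ribosomal and small nucleolar RNA genes, and whether they were precursors was not tested. All 22 isoforms over 45S genes lay on the plus strand in 3 gene copies. Of these, 7 began 47 nt before the annotated gene, 6 ended within 2 nt of the end of the 28S gene and 6 within 2 nt of the end of the 45S gene. Small nucleolar RNA genes were covered by 45 single-exon isoforms over 59 such genes, counted on either strand. At least 1 of these isoforms, over SNORA10, lay antisense to its host gene RPS2. Isoforms over SNORD3B-2 and SNORD3C were also sorted as antisense to a gene. Among them were isoforms that matched the small RNA gene from its first to its last base. Whether the isoform file gave the right strand for single-exon isoforms was not tested. In SNHG1, a single exon of 2297 nt on chromosome 11 from 62851989 to 62854285 spanned SNORD22, SNORD31, SNORD30 and SNORD29, and in GAS5 one of 2570 nt on chromosome 1 from 173863249 to 173865818 spanned SNORD81, SNORD47, SNORD80, SNORD79 and SNORD78.

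Of the tests below, those of the strand of the classification, of annotated junctions among antisense calls, of 5' ends at exon borders and of annotated ends near such borders were chosen after the results were seen. Most minus-strand isoforms were classed as antisense. A candidate explanation is that strand was lost before the classification: it records the plus strand for 99.8% of minus-strand isoforms. All junctions were recorded as canonical in 99.4% (98.7 to 99.8) of spliced plus-strand isoforms, but in 0.939% (0.430 to 1.78) of spliced minus-strand ones. Of 886 spliced plus-strand isoforms, 0 were called antisense. Of the junctions in spliced isoforms called antisense, 99.2% (98.8 to 99.5) are annotated junctions of the strand in the isoform file. Over the junctions of all isoforms the share was 99.1% (98.9 to 99.3). Splice sites had been corrected by the authors' software, so the share of annotated junctions alone cannot decide on transcription from the opposite strand. The 0.939% with canonical junctions, given with the plus strand recorded, argues against it for spliced minus-strand isoforms. This holds as far as the correction did not move junctions to sites of the other strand. Neither value covers single-exon isoforms called antisense. No other explanation was tested.

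Annotated introns were kept in 44.5% of spliced isoforms, in 25.9% when only introns removed in another isoform counted and in 42.2% on the plus strand alone. Isoforms with a whole annotated chain were among these, and 30.9% of them kept an intron of another annotated transcript. The authors' own subcategory gave 2.93%, and 6.09% on the plus strand alone, and why it differs was not tested. If introns transcribed last were simply not yet removed, kept introns would lie nearer the 3' end than removed ones, and they did in 47.9% (43.7 to 52.1) of 564 isoforms, after 46 ties were left out of the 610 that hold both. With introns of like length compared the share was 47.0% (41.9 to 52.1). Both intervals lie below the 60% set in advance for this as the cause, but not wholly below the 50% set in advance to exclude it. Other values go both ways. Last introns were kept in 10.1% (8.24 to 12.1), against 13.5% of all introns at the same lengths, while introns 1000 nt or more from the 3' end were kept less often (11.5%, 10.3 to 12.6) than the 13.0% at the same lengths. A part played by late transcription stays open for canonical introns of protein-coding genes. Ligation of the poly(T) adapter inside A-rich introns was not decided, because a kept intron must have exon on both sides and so does not hold the 3' end after which A content is given. Limited read length may favour short introns: kept introns had 0.377 of the median length of removed ones, above the limit of 1 over 3 that was set in advance for this explanation. With each distinct intron counted once, the medians were 231 nt for kept and 742 nt for removed introns, which falls below that limit. The outcome thus depends on the way of counting. Slower removal of short introns stays open as well, since read length and intron length cannot be told apart here.

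Ends at the last base of exons may mark RNA cut at the 5' splice site, the first step of splicing. Of 352 such 3' ends 97.2% (94.8 to 98.6) lay at a 5' splice site of the canonical transcript, above the 78.6% (77.4 to 79.8) of all annotated 5' splice sites of the same genes. Trimming alike at both ends is argued against by the 3.89% of 5' ends at exon borders against 19.6% of 3' ends. For 3' ends at exon borders, setting of ends to transcript ends of the annotation used here is argued against. Before any were left out, 13.1% of all 3' ends within 2 nt of such a border lay within 100 nt of an annotated end. The 352 were counted without those. The annotation the authors used is not given, so setting of ends to other annotated positions stays open. Trimming that acts at 3' ends alone was not tested and stays open, and it would also favour canonical sites. The share of 3' ends at exon borders was 16.1% on the plus and 23.1% on the minus strand, and why it differed was not tested.

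Single-exon isoforms outside genes of their own strand, 418 in all, may in part begin at promoters of the other strand or follow from genes upstream. Their 5' end lay within 1000 nt of an annotated start of the opposite strand in 15.8% (12.4 to 19.6), against 4.25% at shuffled positions, and within 5000 nt after the end of a gene of their strand in 18.4% (14.8 to 22.5), against 5.53%. Both shares were above those of shuffled positions and below the 25% set in advance for either as the main source. Positions were shuffled along the same chromosomes, whereas 163 of the isoforms lay opposite a gene by definition. The shuffled shares are therefore no measure of chance for such isoforms. The strand of these single-exon isoforms was that of the isoform file and was not tested. Of the 418 isoforms, 72 lay over ribosomal or small RNA genes, which the gene models used here mostly lack.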
